A study of Mus musculus with 18 samples.

How the data were processed

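Total RNA from mouse embryonic fibroblasts (MEFs), liver and adipose tissue of wild-type (WT) and Cav1 knockout (KO) mice was measured on 18 Illumina Mouse-6 V1 BeadChip arrays, 3 per genotype and tissue. Per the labels' protocols, fibroblasts of a primary line were collected 24 hours after plating, liver was taken 24 hours and adipose tissue 11 hours after food was withdrawn, tissues were rinsed of blood with cold PBS and frozen, RNA was purified with an RNAeasy kit, and labelling followed the Illumina TotalPrep amplification kit. Each array was assigned to its genotype and tissue from its title. The labels do not say whether the arrays of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical.

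Per the file headers, the deposited raw values are average bead signal intensities exported from BeadStudio 1.5.1.3 with no normalization and no error model. The deposited detection p-values give, for each probe and array, the share of negative control probes at or above its signal, as the values themselves show. The authors also deposited normalized intensities on a linear scale. In these the 6 arrays of a tissue share 1 distribution, and the submitters' processing notes name lumi, RMA, affy and limma without a role. A further deposited table gives other information, the slide and position of each array. The MEF arrays lay on 1 slide with WT at positions A to C and KO at D to F. The 6 adipose arrays lay interleaved on 1 slide. In liver, WT replicate 1 lay on a different slide from the other 5 arrays, which had WT at positions B and C and KO at D to F.

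Of 45992 probes, 75 controls were left out. No table used here pairs probes with genes, and names were inferred. The number inside many probe names was read as an NCBI gene ID and looked up in a RefSeq gene table of the mouse assembly GRCm38.p6, which was used only for names and chromosomes. This named 9807 probes. A RefSeq accession named 9, a RIKEN clone listed as a synonym named 978, and the table's own name was kept for 14, which left 35109 probes without a name. The reading was tested on the data. Of 11868 such numbers, 82.6% matched a gene ID, against 41.1% to 46.2% when the numbers were shifted by -2, -1, 1, 2 or 7. Of 53 marker probes named this way, 46 (86.8%) were brightest in their own tissue. With shifted numbers this share was 38.1% to 78.6% of 20 to 31 probes, so the marker check separates less clearly than the match of IDs. Every gene name below rests on this inference, and an individual name can still be wrong.

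Values were computed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background by normexp with negative controls inferred from the detection p-values, added an offset of 16, quantile normalized the 6 arrays of a tissue together and took log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which kept 14048 in MEFs, 12573 in liver and 15967 in adipose tissue. KO was compared with WT in each tissue separately with lmFit and eBayes, two-sided, and probes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. All adjusted p-values for single probes and genes come from limma. Errors are the standard error (SE) of the log2 difference or the standard deviation (SD) of 3 arrays. The inferred negative controls included a few very bright ones, so the background SD fitted by limma was 112.4 to 507.0 raw units per array, against a median absolute deviation of 11.7 to 23.0 for the same controls. Differences of dim probes are therefore compressed toward 0. A background set from the median and the median absolute deviation was added as an alternative after the data were seen. Where a probe was not detected on any array of 1 genotype, the fold is a lower bound. On the log2 scale it is the mean of the other genotype minus the mean over the undetected arrays of the higher of the probe's own value and that array's lowest detected value.

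Before the data were examined, 29 gene lists and 18 lists of cell type markers were fixed. Lists with at least 3 measured genes were tested with camera (preset correlation between genes 0.01, the brightest probe per gene), adjusted over the lists of that tissue. The same test with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance, were run as alternatives. No list passed in any tissue with the estimated correlation. Named genes follow a rule fixed beforehand. They are Cav1, the 10 largest changes in each direction among named genes past the threshold whose groups did not overlap, up to 4 members of each list that passed or held at least 3 called genes, the measured caveola components, and genes called in the same direction in all 3 tissues. Some genes that meet this rule are not reported here. Differences of the knockout effect between tissues were tested in 1 limma fit over all 18 arrays, and overlaps of called genes with Fisher's exact test, two-sided.

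The alternatives were no background correction, the authors' normalized values, median centring, joint normalization of 18 arrays, no filter or a stricter filter (detection p under 0.01), 1 fit over 18 arrays, a trended and robust variance model, array weights, probes averaged per gene, the slide or the replicate number as a block, and leaving out each array. The section of the adipose slide (positions A to C, D to F) as a block, and overlaps and differences between tissues with the replicate block in MEFs, were added after the data were seen. Replicate numbers 1, 2 and 3 are shared by both genotypes in MEFs and liver. The correlations of same-numbered arrays, as deviations from their group means over probes, were 0.101, 0.227 and 0.238 in MEFs. All were above the limit of 0.1 set for treating the numbers as pairs, the first of them barely, so the MEF results are also given with the replicate number as a block. The pairing comes from this correlation only, since the labels state none. The liver correlations were 0.228, 0.234 and -0.103, and the adipose groups share 1 number, so these were not treated as pairs.

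The fits were tested on normally distributed simulated data built from the real means and spreads with known changed probes. The changes were added to values already background corrected and normalized, so those steps were not tested. Because the background correction compresses differences of dim probes, the shares recovered can be too high for real changes. The fit of KO against WT recovered 59.7% of probes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 95.5% of those changed by 2 in MEFs, with 12 false calls. The same shares were 61.2%, 88.1% and 98.5% with 6 false calls in liver, and 52.2%, 83.6% and 93.9% with 6 in adipose tissue. The test of differences between tissues made 24, 58 and 45 false calls for MEF and liver, MEF and adipose, and liver and adipose, so it exceeds its nominal error rate. In the same order it recovered 46.3%, 55.2% and 59.7% of probes changed by 0.5. Its counts thus hold too many false calls and also miss small differences. No columns were left unused for want of a sample, and no 2 arrays were duplicates (highest correlation of raw log2 signal 0.989).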

Results

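Gene expression was compared between WT and Cav1 knockout mice in 3 settings, primary embryonic fibroblasts (MEFs), liver after 24 hours without food and adipose tissue after 11 hours without food. Caveolin-1, the product of Cav1, is a main structural protein of caveolae, small invaginations of the plasma membrane that are abundant in adipocytes, fibroblasts and endothelial cells. Each group held 3 arrays, and the question in each tissue was which transcripts differ between KO and WT. The arrays detected 13524 to 14733 probes (29.5% to 32.1%) in MEFs, 12076 to 13131 (26.3% to 28.6%) in liver and 14877 to 16973 (32.4% to 37.0%) in adipose tissue. Correlations between arrays of a tissue were 0.981 to 0.993, 0.969 to 0.995 and 0.947 to 0.988. The first principal component held 42.0%, 56.0% and 53.6% of the variance, and its correlation with genotype was 0.964, 0.977 and 0.874 in size. Adipose KO 5 correlated as well with the WT arrays (mean r 0.9745) as with the other KO arrays (0.9741). The number of arrays, 3 per group, limits the precision of every value. Gene names were inferred from gene IDs inside the probe names.

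The targeted gene was measured first, by 1 probe. In MEFs the raw Cav1 signal was 10792, 9766 and 10821 on the WT arrays and 789, 1163 and 1690 on the KO arrays. In adipose tissue it was 25664, 50304 and 40700 in WT and 1940, 3167 and 2297 in KO. Liver had little Cav1 signal, 158.0, 165.7 and 186.0 in WT against 133.7, 123.2 and 109.6 in KO, and the probe was detected on 1 of 3 KO arrays. Cav1 fell by 3.44 ± 0.26 (log2, SE, n = 3 per group) in MEFs with limma's adjusted p = 0.0160, and fell by 4.38 ± 0.31 in adipose tissue with limma's adjusted p = 0.0155. The difference in liver was -0.23 ± 0.05 with limma's adjusted p = 0.0609, which did not pass. Liver Cav1 passed under 7 of 19 alternatives, and its size depends on how the background is handled. Limma's adjusted p was 0.0231 with no background correction (difference -0.56), 0.0281 with the authors' values (-2.38) and 0.0182 with the alternative background (-1.37), while over all alternatives it ranged from 0.0111 to 0.688. The KO signal in MEFs and adipose tissue stayed above background on every array, and whether the probe lies in the deleted part of the gene is not known here. With the replicate number as a block the MEF adjusted p was 0.0931. It was 0.0503, 0.0961, 0.0774 and 0.100 without MEF WT 1, WT 2, WT 3 and KO 2, and the adipose value was 0.0756, 0.0867, 0.0789 and 0.0589 without adipose WT 1, WT 2, WT 4 and KO 3. With the section of the adipose slide (positions A to C, D to F) as a block, a test chosen after seeing the data, the adipose value was 0.0627 (difference -4.32).

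**Figure D1:**
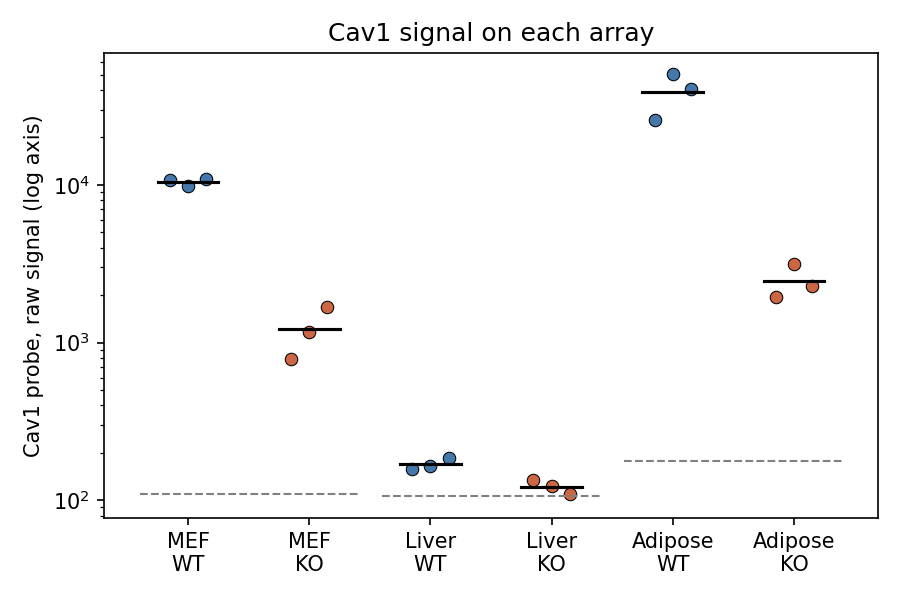
Raw signal of the Cav1 probe (log axis) on each of the 18 arrays by tissue and genotype; points are arrays, solid bars group means and dashed lines the mean of the arrays' median negative control signal. The KO arrays lie between 789 and 1690 in MEFs and between 1940 and 3167 in adipose tissue, below all WT arrays, and all liver arrays lie between 109.6 and 186.0.

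In Cav1 knockout MEFs the largest decreases among named genes past the threshold, apart from Cav1, were those of Mgp, Col1a2 and Cox7a2l. Mgp, which encodes the calcification inhibitor matrix Gla protein, fell by 3.15 ± 0.25 (log2, SE), from 12.03 ± 0.10 to 8.88 ± 0.50 (SD, n = 3). Col1a2, the alpha 2 chain of type I collagen, fell by 3.06 ± 0.24, while Col1a1 differed by 0.07 ± 0.15 and Col3a1 by -0.30 ± 0.34, neither past the threshold. Cox7a2l, a factor of respiratory supercomplexes, fell by 2.84 ± 0.05, and Dlk1, the preadipocyte factor, fell by 2.17 ± 0.11. Emb, encoding embigin, was detected on all WT and on 0 of 3 KO arrays, at least 4.01-fold lower. Fgfr1op2 (-1.97), the proteasome subunit gene Psmd8 (-1.27), Klhdc4 (-1.15) and the mitochondrial ribosome gene Mrps12 (-1.06) fell as well. A dim second probe for Fgfr1op2 differed by 0.02. Mgp, Col1a2 and Fgfr1op2 lie on chromosome 6, which also carries Cav1. Among named genes the rises were led by that of the ARF-like GTPase gene Arl5a (1.58 ± 0.18), and others were those of the sorting nexin gene Snx5 (0.62), the histone variant gene H2az1 (0.59), Plekha1 (0.43) and the lysyl oxidase gene Loxl2 (0.41). Limma's adjusted p for these 14 genes lay between 0.000158 (Cox7a2l) and 0.0443 (Arl5a). Of 18 named genes past the threshold 7 stayed called in every fit that left out 1 array and tested them (Cox7a2l, H2az1, Dlk1, Emb and Fgfr1op2 among them), and Snx5, Plekha1, Loxl2 and Klhdc4 were called in none of these fits.

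In all, 63 of 14048 probes passed in MEFs, 19 higher and 44 lower in KO, of which 26 were named. The largest change of all was the rise of an unnamed probe, by 4.16 ± 0.11, picked out after its values were seen. At the 2-fold level 11 higher and 20 lower probes changed. An unadjusted p under 0.05 was reached by 1507 probes where 702 would be expected by chance, and WT and KO did not overlap for 16.9% of probes, against 10% by chance. With the replicate number as a block 9 probes passed (4 higher, 5 lower), of which 8 were among the 63, and of 18 named genes past the threshold 4 passed, Cox7a2l, Emb and Fgfr1op2 among them. All WT arrays lay at slide positions A to C and all KO arrays at D to F, so position cannot be told apart from genotype in any MEF value. The count was 17, 19, 23, 21 and 40 without MEF WT 2, WT 3, KO 1, KO 2 and KO 3, and with no background correction 114 were higher and 157 lower. Without MEF WT 1 the count was 61, of which 22 were among the 63.

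Of 22 gene lists with at least 3 measured genes in MEFs, 4 passed camera. With an estimated correlation all 4 calls were lost, with an adjusted p of 0.389 for the cell cycle and 0.530 for the other 3 lists, and with fry the cholesterol and fatty acid calls were lost (adjusted p = 0.275 for both), while inflammatory mediators passed (lower, adjusted p = 0.0490). Genes of cholesterol synthesis rose as a group, all 16 measured members being higher in KO, with a median of 0.17 (adjusted p = 3.8e-05). Acat2 differed by 0.81 ± 0.21, Cyp51 by 0.56 ± 0.22, and both Hmgcs1, the HMG-CoA synthase gene, and Fdps by 0.45 ± 0.18, and no member passed alone, also when adjusted over the list alone. The list of fatty acid and triglyceride synthesis rose (5 of 6 positive, median 0.22, adjusted p = 0.0273), with Elovl6 at 0.50 ± 0.13, Acly at 0.29, Fads2 at 0.25 and Acss2 at 0.18. With 1 array left out the median of this list ranged from 0.14 to 0.29, Acly from 0.17 to 0.40 and Fads2 from 0.11 to 0.36. Cell cycle genes fell (11 of 12 negative, median -0.25, adjusted p = 0.00146), with the thymidine kinase gene Tk1 at -0.58 ± 0.10, Cenpa at -0.51 ± 0.10, Mcm7 at -0.30 and Ccnb1 at -0.27. These 4 were the members past the threshold adjusted over the list alone, and 0 passed over all probes. Glycolysis genes fell (10 of 12 negative, median -0.10, adjusted p = 0.0494), with Gpi1 at -0.31 ± 0.04 (a dimmer second probe at 0.32), Pgk1 at -0.26, Pfkm at -0.22 and Pfkfb3 at -0.13, and 2 members passed when adjusted over the list alone. With the replicate block the glycolysis list had an adjusted p of 0.0596. The glycolysis call was lost under 15 of 20 alternatives, and the fatty acid call under 6, including leaving out MEF KO 1, while the cell cycle call was lost without MEF KO 3, so that 2 lists passed when either of these arrays was left out.

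The caveola components measured in MEFs did not pass, with Cavin1 at 0.17 ± 0.09, Ehd4 at -0.24 ± 0.18 and Pacsin3 at 0.05 ± 0.06 (list adjusted p = 0.798). Over the alternatives MEF Cavin1 ranged from 0.08 to 0.73 without passing, so its size depends on the processing. The 1 probe named Cav2 was at background on every array of every tissue, also on the WT arrays with bright Cav1. Whether this probe reads Cav2 was not tested, so it does not show whether Cav2 is expressed. The other 17 lists tested, among them extracellular matrix, oxidative phosphorylation, heat shock, p53 and senescence, interferon response, insulin and IGF signalling, and fibroblast and macrophage markers, had adjusted p from 0.1498 to 0.958. The extracellular matrix list in MEFs held 1 called gene (Col1a2), and 3 adjusted over the list alone. These were Col1a2, Eln at -1.33 ± 0.21 and Thbs1 at 1.44 ± 0.40. The X-linked Xist (1 of 2 probes) and the Y-linked Eif2s3y were detected on all 6 MEF arrays, and Eif2s3y ranged from 179.2 to 539.1 raw units in KO against 239.7 to 311.1 in WT.

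In Cav1 knockout liver after food withdrawal the largest fall among named genes past the threshold was that of Serpina1e and the largest rise that of Cyp2c29. Serpina1e, one of several near-identical alpha-1-antitrypsin genes of the mouse, fell by 5.58 ± 0.26 (log2, SE), from 14.37 ± 0.37 to 8.79 ± 0.38 (SD, n = 3). Mug2, a murinoglobulin, fell by 3.22 ± 0.24, and Acot3, an acyl-CoA thioesterase, fell by 3.07 ± 0.25. Serpina12, which encodes vaspin, was detected on 0 of 3 KO arrays and was at least 4.88-fold lower. The small heat shock protein gene Hspb1 fell by 2.36 ± 0.36, Ddah1, whose product degrades an inhibitor of nitric oxide synthase, fell by 2.15 ± 0.28, and the glucuronosyltransferase gene Ugt1a9 fell by 2.11 ± 0.32. Fgfr1op2 (-1.76), the signal recognition particle receptor gene Srpr (-1.76) and Pnpla7 (-1.50) fell too, although a second, equally bright Srpr probe differed by 0.04. The cytochrome P450 gene Cyp2c29 rose by 3.19 ± 0.54, 9.10-fold, the uridine phosphorylase gene Upp2 by 2.01 ± 0.34 and Serpina11 by 1.89 ± 0.05. Tns1 (1.44), Retreg1 (1.12), Serpina3m (1.06), Afmid (1.01), Pik3r1 (0.99), a regulatory subunit of phosphoinositide 3-kinase, Pheta1 (0.93) and Apol9b (0.87) also rose. Limma's adjusted p lay between 0.000147 (Fgfr1op2) and 0.0421 (Pik3r1). With 1 array left out, 7 of 27 named genes past the threshold stayed called in every fit that tested them (Serpina11, Serpina1e, Mug2, Acot3, Serpina12, Fgfr1op2 and Srpr), and Ldha and Cycs, named below, were called in none.

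Liver had the most calls, 590 of 12573 probes, 247 higher and 343 lower, 189 of them named, with 50 higher and 64 lower by at least 2-fold. The largest rise was that of an unnamed probe (4.75 ± 0.39), picked out after its values were seen. An unadjusted p under 0.05 was reached by 2789 probes against 629 expected, and the groups did not overlap for 27.9% of probes against 10% by chance. The count fell to 275, 141, 61, 181 and 209 without liver WT 1, WT 2, WT 3, KO 2 and KO 3 and rose to 1066 without KO 1, and with the slide as a block it was 292 (123 higher, 169 lower), of which 226 were among the 590. On the slide that held 5 of the liver arrays, WT lay at positions B and C and KO at D to F, so position is not separated from genotype there either. With the background set from median and median absolute deviation, 307 were higher and 266 lower, and the excess of lower probes was also absent with no background correction (419 higher, 418 lower), the authors' values (189 and 183) and a trended robust variance (415 and 398).

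Of 26 lists tested in liver, 7 passed camera. All 7 calls were lost with an estimated correlation, with an adjusted p of 0.738 for beta-oxidation and 0.545 for the other 6, and fry called none (lowest adjusted p 0.0620). Oxidative phosphorylation genes fell (9 of 12 negative, median -0.26, adjusted p = 0.00420), and 3 members passed over all probes, the cytochrome oxidase subunit gene Cox5b (-0.32 ± 0.04), Ndufs3 (-0.32 ± 0.06) and the cytochrome c gene Cycs (-0.40 ± 0.08). Sdhc, at -0.41 ± 0.09, was among 6 that passed when adjusted over the list alone. Fatty acid beta-oxidation genes fell (7 of 7 negative, median -0.24, adjusted p = 0.0164), with the trifunctional protein gene Hadhb called (-0.53 ± 0.05), and Acaa1a at -0.33 and Etfa at -0.20, and 3 members passed over the list alone. PPAR-alpha targets fell (4 of 4 negative, median -0.68, adjusted p = 0.0128), with Acsl1 at -0.71 ± 0.15, Angptl4 at -0.59 ± 0.14 and Cyp4a10 at -0.64 ± 0.18, these 3 past the threshold over the list alone. Glycolysis genes fell (10 of 11 negative, median -0.33, adjusted p = 0.00431), with Ldha called (-0.42 ± 0.08), Eno1 at -0.70, Pfkm at -0.47 and Tpi1 at -0.16, all 4 over the list alone.

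Heat shock genes in liver fell (6 of 6 negative, median -0.31, adjusted p = 0.0132, and adjusted p = 0.545 with an estimated correlation, as for the next 2 lists), led by Hspb1, with Hsp90aa1 at -0.90 ± 0.26, Hspd1 at -0.23 and Hspe1 at -0.36, and 2 passed over the list alone. Xenobiotic metabolism genes rose (7 of 7 positive, median 0.82, adjusted p = 0.00420), with Cyp2c29 called, Cyp2a5 at 1.10 ± 0.22, Cyp2c37 at 2.05 ± 0.60 and Cyp2a4 at 0.57 ± 0.24, and 3 passed over the list alone. Acute phase genes rose (5 of 5 positive, median 0.90, adjusted p = 0.00853), with the C-reactive protein gene Crp at 0.45 ± 0.09, Cp at 0.90 ± 0.29, Saa1 at 2.70 ± 0.87 and Saa2 at 1.03 ± 0.52. Of these 0 were called over all probes and 3 over the list alone. With 1 array left out the acute phase median ranged from 0.48 to 1.09 and Saa2 from 0.48 to 1.54. The beta-oxidation call was also lost with the authors' values, with median centring, with the alternative background, without WT 2 and without KO 1, the heat shock call without KO 2, the glycolysis and PPAR-alpha calls with median centring, and the PPAR-alpha call with no filter.

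The other 19 liver lists had adjusted p from 0.0514 to 0.918. The lowest was that of NRF2 targets (median 0.73, 3 of 4 positive), and hepatocyte, endothelial, macrophage and epithelial markers, cholesterol, bile acid and fatty acid synthesis, gluconeogenesis, the male and female liver genes, the circadian clock and the interferon response were among them. The list of female liver genes held Acot3, which was called lower, while its other 2 members were positive. Pacsin3 differed by 0.27 ± 0.14 and Ehd4 by 0.01 ± 0.11 in liver, neither past the threshold, and the sign for Ehd4 changed under 5 alternatives and without either WT 3 or KO 1. The haemoglobin transcripts Hbb-b1 and Hba-a1, markers of blood in the tissue, differed by -1.84 ± 0.49 and -1.77 ± 0.58, with limma's adjusted p = 0.100 and 0.153.

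In Cav1 knockout adipose tissue the largest rises among named genes past the threshold were those of Bok, Vcam1 and H2-T10. Bok, a Bcl-2 family gene, rose by 2.95 ± 0.31 (log2, SE), from 9.31 ± 0.44 to 12.26 ± 0.44 (SD, n = 3), 7.74-fold. Vcam1, a leukocyte adhesion molecule, rose by 1.59 ± 0.08, and the class I histocompatibility gene H2-T10 by 1.57 ± 0.09. The phosphatase gene Ptp4a2 (1.11), the IGF binding protein gene Igfbp4 (1.11), Ccdc80 (1.08), Tnip1 (1.00), an inhibitor of NF-kB signalling, the prolactin receptor gene Prlr (0.89) and Tmem68 (0.83) also rose. Fgfr1op2 fell by 2.63 ± 0.06, Cdkl2 fell by 1.94 ± 0.07 and Srpr by 1.90 ± 0.05, although a second Srpr probe differed by 0.06. Zfp131 fell by 1.58 ± 0.09 and Atpsckmt by 1.19 ± 0.07. Smaller falls were those of the mitochondrial kinase gene Pink1 (-0.61), Eya3 (-0.54), Cbfa2t3 (-0.51), Gapdh (-0.48) and the mitochondrial ribosome gene Mrpl20 (-0.40). Limma's adjusted p lay between 0.000297 (Fgfr1op2) and 0.0457 (Ccdc80). Only 3 of 21 named genes past the threshold stayed called in every fit with 1 array left out (Fgfr1op2, Cdkl2 and Srpr), and the calls for Igfbp4, Ccdc80, Tnip1, Pink1, Gapdh and Mrpl20 were lost in all 6.

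In adipose tissue 65 of 15967 probes passed, 36 higher and 29 lower, 26 of them named, with 18 in each direction changed at least 2-fold. The largest rise (5.12 ± 0.12) and the largest fall (-5.95 ± 0.04) were those of unnamed probes, picked out after their values were seen. An unadjusted p under 0.05 was reached by 2111 probes against 798 expected, and the groups did not overlap for 19.6% against 10% by chance. The count was 8, 18, 23, 28 and 22 without adipose WT 1, WT 2, WT 4, KO 2 and KO 3, and with no filter on dim probes 13 were higher and 17 lower. Without adipose KO 5 the count was 93, of which 39 were among the 65. The genotypes were spread over both sections of the adipose slide. With the section (positions A to C, D to F) as a block, chosen after seeing the data, 31 probes passed (12 higher, 19 lower), of which 28 were among the 65, and 6 lists passed. Among the calls lost was that of Bok (adjusted p = 0.109).

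Of 26 lists tested in adipose tissue, 6 passed camera. None of the 6 was kept with an estimated correlation, with an adjusted p of 0.375 for glycolysis, 0.523 for inflammatory mediators and 0.618 for the other 4, and with fry the calls for oxidative phosphorylation, fatty acid synthesis and beta-oxidation (adjusted p = 0.119 for all 3) and matrix (0.335) were lost. All 11 measured glycolysis genes were lower in KO (median -0.51, adjusted p = 2.23e-07), with Aldoa at -0.73 ± 0.10, the phosphofructokinase gene Pfkl at -1.05 ± 0.18, Gpi1 at -0.67 ± 0.12 and Pgk1 at -0.39 ± 0.07. None passed over all probes and 8 passed when adjusted over the list alone. All 12 measured oxidative phosphorylation genes were lower (median -0.45, adjusted p = 1.89e-06), with Cox6c at -0.40, Ndufb8 at -0.46, Sdhb at -0.75 and Atp5c1 at -0.40, and 3 passed over the list alone. Fatty acid and triglyceride synthesis genes fell (5 of 7 negative, median -0.58, adjusted p = 0.0119), with the elongase gene Elovl6 at -2.51 ± 0.34, Acly at -0.72, Acaca at -0.98 and the fatty acid synthase gene Fasn at -0.54, all 4 over the list alone. Fatty acid beta-oxidation genes fell (7 of 7 negative, median -0.15, adjusted p = 0.0133), with Hadhb at -0.66 (the 1 gene past the threshold over the list alone), Etfa at -0.45 and Acadl at -0.08. With 1 array left out the beta-oxidation median ranged from -0.246 to -0.065. The number of adipose lists past the threshold was 10 without WT 2 and 10 without KO 5.

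**Figure D2:**
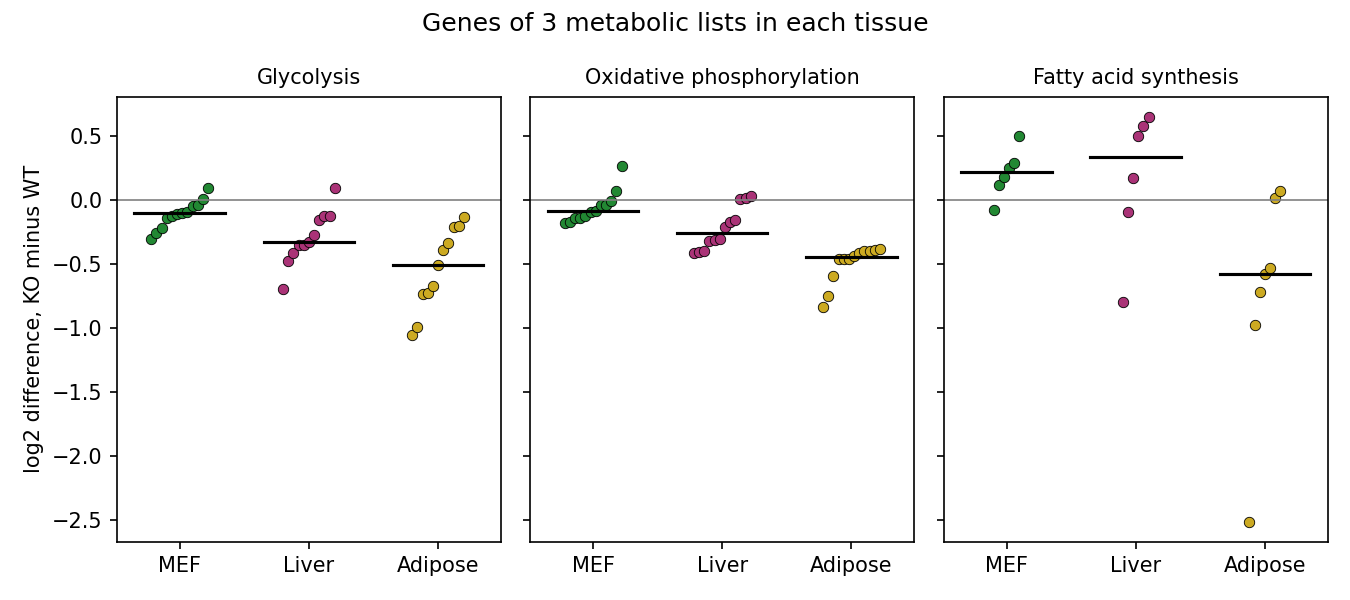
Log2 difference (KO minus WT) of the measured genes of 3 lists in each tissue; points are genes and bars medians. All 11 glycolysis and all 12 oxidative phosphorylation genes lie below 0 in adipose tissue, with medians of -0.51 and -0.45, and the fatty acid synthesis list has medians of 0.22 in MEFs and -0.58 in adipose tissue, its liver value (0.34) not being past the threshold.

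Of the same 6 adipose lists, extracellular matrix genes rose (7 of 9 positive, median 0.94, adjusted p = 0.0119), with Col5a1 at 0.94 ± 0.26, Dcn at 0.88 ± 0.27, Loxl1 at 1.22 ± 0.47 and Col6a3 at 0.93 ± 0.36, none called over all probes or over the list alone, and the adjusted p was 0.618 with an estimated correlation. Inflammatory mediators rose (3 of 3 positive, median 0.27, adjusted p = 0.00828, and adjusted p = 0.523 with an estimated correlation), with Vcam1 called, Tlr4 at 0.27 ± 0.07 and Cxcl1 at 0.09 ± 0.13, the last turning negative without KO 3. Of these Vcam1 and Tlr4 passed over the list alone. The matrix call was also lost without WT 1 and without KO 2, the beta-oxidation call without WT 1 and in 1 fit over 18 arrays, and the inflammatory call with no filter.

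Markers of other cell types moved apart in adipose tissue without passing the list test. All 5 macrophage markers were higher (median 0.67, adjusted p = 0.0710), all 6 endothelial markers lower (median -0.30, adjusted p = 0.0688), 4 of 5 fibroblast markers higher (0.88, adjusted p = 0.141) and all 3 mesothelial markers higher (0.87, adjusted p = 0.127), while 7 of 10 adipocyte genes were lower (median -0.10, adjusted p = 0.242). The other adipose lists, among them heat shock, PPAR-alpha targets, cholesterol synthesis, cell cycle, interferon response and insulin and IGF signalling, had adjusted p from 0.0993 to 0.859. The heat shock list (median -0.34, 4 of 6 negative) passed with fry (lower, adjusted p = 0.0168), and 3 of its members passed over the list alone. Caveola components did not pass, with Cavin1 at 0.15 ± 0.06, Ehd4 at 0.30 ± 0.18 and Pacsin3 at -0.12 ± 0.21 (list adjusted p = 0.373), the last changing sign without WT 1 or KO 3. Adipose Cavin1 ranged from 0.10 to 1.83 over the alternatives without passing, so the size of its difference depends on the processing.

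Fgfr1op2 and Eya3, a transcriptional coactivator and phosphatase, were called lower in all 3 tissues. In MEFs, liver and adipose tissue in turn the differences were -1.97 ± 0.09, -1.76 ± 0.04 and -2.63 ± 0.06 for Fgfr1op2 and -0.46 ± 0.04, -0.47 ± 0.08 and -0.54 ± 0.04 for Eya3. Fgfr1op2 stayed called in every fit with 1 array left out and with the replicate block in MEFs (adjusted p = 0.0200). Eya3 was called in 1, 2 and 1 of 6 fits with 1 array left out, and its MEF call was lost with the replicate block (adjusted p = 0.0921). The sizes depend on the processing. With probes averaged per gene Fgfr1op2 was at -0.97, -0.93 and -1.36, because a dim second probe differed by 0.02, -0.10 and -0.09, and with the authors' values Eya3 was at -2.40, -2.12 and -2.03. Fgfr1op2 lies on chromosome 6 with Cav1. With unnamed probes included, 10 probes were called in the same direction in all 3 tissues (4 higher, 6 lower) against 0.00255 expected from independent lists over 9772 probes tested in all 3. The largest of these changes was that of the unnamed probe with the largest rise in MEFs and in adipose tissue. It rose by 4.16, 4.74 and 5.12 in MEFs, liver and adipose tissue. The unnamed probe with the largest rise in liver (4.75) is a different one. With the replicate block in the MEF fit, a test chosen after seeing the data, 5 of these 10 remained. No probe was called in opposite directions in any pair of tissues. In pairs, Eif2s2 (-0.89 and -0.999) fell in MEFs and liver, Atpsckmt (-1.47 and -1.19) and Srpr (-1.76 and -1.90) fell in liver and adipose tissue, and Tmem68 rose in both (0.72 and 0.83).

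**Figure D3:**
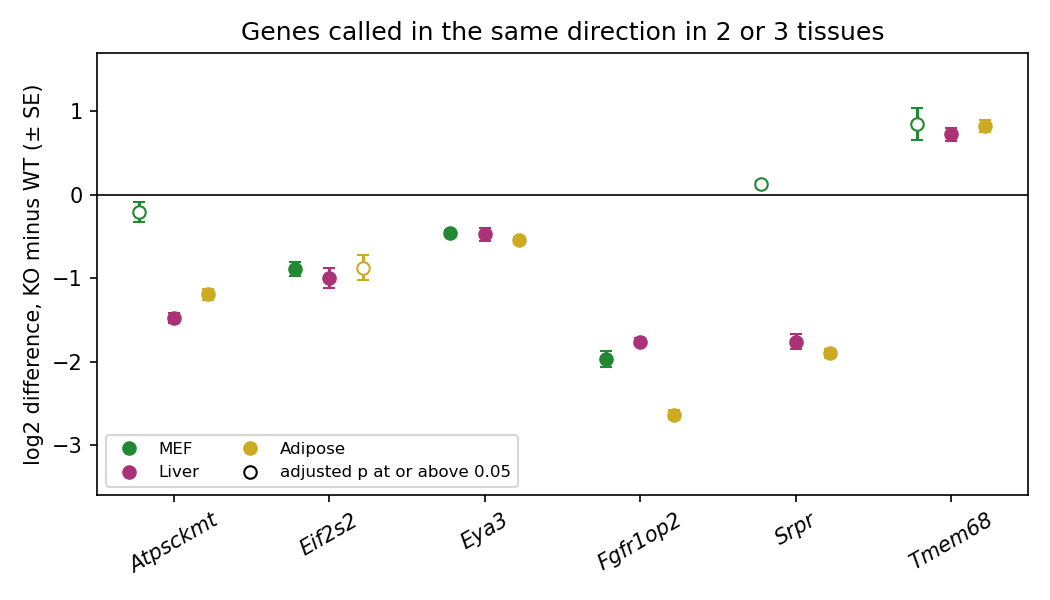
Log2 difference (KO minus WT, ± SE, n = 3 per group) in each tissue of 6 named genes other than Cav1 that passed in the same direction in 2 or 3 tissues; filled points passed the threshold. Fgfr1op2 and Eya3 lie below 0 in all 3 tissues, and Srpr lies at 0.13 in MEFs against -1.76 in liver and -1.90 in adipose tissue.

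The overlap of called genes was tested per direction and pair, 6 tests in all. Lower genes shared by MEFs and liver numbered 4 where 0.454 were expected (Fisher's exact test, adjusted p = 0.00167), those shared by MEFs and adipose tissue 3 where 0.0522 were expected (Cav1 among them, exact test, adjusted p = 8.5e-05) and those shared by liver and adipose tissue 4 where 0.302 were expected (exact test, adjusted p = 0.000431). Higher genes shared numbered 1, 1 and 2 where 0.0939, 0.0214 and 0.239 were expected, with adjusted p of 0.0905, 0.0273 and 0.0273 by the exact test. The tissues share no arrays. These counts use the MEF fit without the replicate block. With the block, chosen after seeing the data, the lower genes shared numbered 1 for MEF and Liver and 1 for MEF and Adipose (exact test, adjusted p = 0.0597 and 0.0165).

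The knockout effect differed between MEFs and liver for 348 of 10387 probes, between MEFs and adipose tissue for 375 of 11964 and between liver and adipose tissue for 511 of 10949. MEFs were cultured, liver and adipose tissue were taken after different times without food, and each tissue lay on its own slides. The median negative control signal was 166.9 to 183.6 on the adipose arrays, against 103.4 to 114.4 in MEFs and 100.3 to 111.8 in liver. Differences of dim probes may thus be compressed unequally, which was not tested. The counts cannot tell an effect of tissue from these conditions. The fits behind the counts ignore the replicate numbers. With the replicate number as a block within MEFs, a test chosen after seeing the data, the counts were 324 for MEF and Liver (277 of them among the 348) and 376 for MEF and Adipose (314 among the 375). Dlk1 and Mgp had lower effects in MEFs than in liver, by -2.15 ± 0.11 and -3.28 ± 0.65, and Mgp and Igfbp4 differed by -4.63 ± 0.65 and -2.59 ± 0.32 between MEFs and adipose tissue. Elovl6 (3.01 ± 0.33) and Acly (1.01 ± 0.21) had higher effects in MEFs than in adipose tissue. Hspb1 (-2.68 ± 0.47) and Bok (-3.43 ± 0.35) had lower effects in liver than in adipose tissue. The Cyp2c29 effect was lower in MEFs than in liver by -3.18 ± 0.49. A gene that is dim in 1 tissue has little room to change there, and this was not examined for these genes. Cav1 itself differed by -3.21 between MEFs and liver and by 4.14 between liver and adipose tissue, where liver had little Cav1 signal and the size of its liver difference depends on the background handling. Limma's adjusted p for these differences lay at or below 0.0213. The first count was 195, 221, 191, 205 and 528 without MEF WT 2, MEF WT 3, MEF KO 2, liver WT 3 and liver KO 1, the count for MEF and Adipose 215, 235, 246, 242 and 845 without MEF WT 2, MEF KO 2, adipose WT 1, KO 2 and KO 5, and that for Liver and Adipose 799, 331 and 797 without liver KO 1, adipose WT 1 and adipose KO 5. Simulated data gave false calls in this step above its nominal rate, and with the alternative background the counts were 185 (MEF and Liver), 221 (MEF and Adipose) and 284 (Liver and Adipose).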

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

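The tests of chance overlap, chromosome 6, the adipocyte share and the NeoR probe were chosen only after the result was seen, as was the test of a single KO array for oxidative phosphorylation, while that test for glycolysis in adipose tissue was set before its value was known.

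The NeoR probe, a neomycin resistance control, had a mean raw signal of 259.5 on the MEF KO arrays against 118.1 in WT and of 558.9 on the adipose KO arrays against 191.3 in WT, detected on all KO and no WT arrays. In liver it was 108.2 in KO and 99.4 in WT, not detected. Stray signal shared by the control probes of KO arrays is argued against, since 0 of 74 other control probes were detected on all KO and no WT arrays of MEF and adipose tissue. That count cannot exclude stray signal of the NeoR probe alone. Transcription at the targeted locus may explain the NeoR signal. Its prediction was written after these values were seen and restates them, so it adds no support. On liver KO arrays, where Cav1 is dim in WT, the lowest detection p of the NeoR probe was 0.361. How the allele was built is not given in the sources used here. In the same KO arrays the Cav1 probe stayed above background in MEFs and adipose tissue, and the cause was not tested.

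The knockout effect differed between tissues for genes named above, and time without food, slide and background signal differed between the tissues as well. For Cav1 the effect in MEF minus liver was -3.21 and in liver minus adipose 4.14, and Cav1 is dim in WT liver, which leaves little room for a fall. The liver difference itself went from -0.23 to -2.38 with the authors' values and to -1.37 with the alternative background, so the size of these gaps rests on the background handling. For Fgfr1op2, MEF minus adipose was 0.66 and liver minus adipose 0.87, all 3 effects being negative. Fgfr1op2 is dim in KO, where the background correction compresses differences, and how much of the gap comes from that was not tested. For Elovl6 and Acly, MEF minus adipose was 3.01 and 1.01, with positive values in MEFs that did not pass alone and negative ones in adipose tissue that did not pass alone either.

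The probes called in the same direction in all 3 tissues numbered 10, where 0.00255 were expected from independent lists, so chance overlap of independent lists is argued against, and 5 of the 10 remained with the replicate block in the MEF fit. In MEFs slide position goes with genotype, while the adipose genotypes are spread over the slide. Alleles linked to the targeted locus on chromosome 6 could give such a pattern if the KO strain carries flanking sequence of another strain. Among named genes called in the same direction in at least 2 tissues 25% (2 of 8) lie on chromosome 6, against 4.89% of 5035 other genes (Fisher's exact test, p = 0.0554, adjusted p = 0.0739), so this cannot be told from chance here. Among genes called per tissue the share was 16% in MEFs (exact p = 0.0285, adjusted p = 0.0651), 7.57% in liver (exact p = 0.0800) and 16% in adipose tissue (exact p = 0.0326, adjusted p = 0.0651). A sequence difference under a probe could also lower its signal in all tissues. For Srpr a second probe of similar brightness differed by 0.04 in liver where the first fell by 1.76. The first Srpr probe did not fall in MEFs (0.13 ± 0.04, limma's adjusted p = 0.318), so its signal was not lowered in all tissues. Probe sequences were not analysed here. Several of the shared genes do not lie on chromosome 6, such as Eya3 (chromosome 4), Srpr (chromosome 9) and Atpsckmt (chromosome 15). A strain difference between WT and KO beyond chromosome 6 was not tested, and these data cannot tell it from the loss of Cav1.

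The lower glycolysis and oxidative phosphorylation genes in adipose KO could come from a lower share of adipocytes, which would raise the markers of every other cell type. The endothelial markers had a mean of -0.35 ± 0.12 (SE over 6 genes) beside 0.65 ± 0.17 for the macrophage markers, so not every other list rose. The fibroblast (0.72 ± 0.35) and mesothelial (0.87 ± 0.42) markers were higher. None of these lists passed the list test, and an SE over genes leaves out the spread between arrays. Of the adipocyte genes themselves 7 were lower and 3 higher, with a median of -0.10 (camera, adjusted p = 0.242). That fall was smaller than the medians of glycolysis (-0.51) and oxidative phosphorylation (-0.45). The adipocyte genes thus do not show a loss of that size, and their directions were mixed. A lower share of adipocytes is left open. The lower glycolysis and oxidative phosphorylation values could also come from a single KO array. The glycolysis median was -0.44 without adipose KO 5 and lay further from 0 without KO 2 or KO 3, against -0.51 with all arrays. The oxidative phosphorylation genes had a mean of -0.36 ± 0.03 (SE over 12 genes) and a median of -0.34 without KO 2, the array whose omission brought them closest to 0, against a median of -0.45 with all arrays. This SE is over genes on the same arrays and does not measure the spread between KO arrays. The means and medians argue against one KO array as the whole source, while KO 2 adds to the size of the oxidative phosphorylation fall. A change in several cell types at the same time was not tested.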

How the results depend on the processing

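The background set from median and median absolute deviation, the overlap counted in probes, the section of the adipose slide as a block and the overlaps and differences between tissues with the replicate block in MEFs were tests chosen only after the result was seen, and all others were fixed before the data were examined.

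In MEF the true analysis gave 19 higher and 44 lower. No background correction gave 114 and 157, the authors' values 33 and 57, no filter 11 and 25, 1 fit over 18 arrays 193 and 217, a trended robust variance 90 and 148, array weights 47 and 77, and the alternative background 66 and 99. Of the 63 calls, 59 were found again with no background correction, 38 with the authors' values and 51 with the alternative background. The replicate block, which treats same-numbered arrays as paired, gave 4 and 5, and with this block Cav1 was at -3.44 with an adjusted p of 0.0931. Leaving out 1 array gave 6 to 25 higher and 11 to 36 lower, 2 to 4 lists, and Cav1 from -3.69 to -3.18. Over all alternatives the adjusted p of Cav1 ranged from 9.09e-07 to 0.100. Lists past the threshold numbered 2 with no filter, with 1 fit over 18 arrays and with averaged probes, and 0 with an estimated correlation. Averaging probes turned Gpi1 to 0.0087.

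In Liver the true analysis gave 247 higher and 343 lower. No background correction gave 419 and 418, the authors' values 189 and 183, no filter 145 and 212, 1 fit over 18 arrays 681 and 664, a trended robust variance 415 and 398, array weights 539 and 648, the slide as a block 123 and 169, and the alternative background 307 and 266, so the excess of lower probes is not stable. Of the 590 calls, 495 were found again with no background correction, 220 with the authors' values and 337 with the alternative background. The replicate number as a block gave 118 and 141, although liver numbers do not pair by their correlations. Leaving out 1 array gave 21 to 541 higher and 40 to 525 lower, 6 to 8 lists, and Cav1 from -0.26 to -0.21. Cav1 passed with no background correction (-0.56, adjusted p = 0.0231), the authors' values (-2.38, 0.0281), joint normalization (-0.30, 0.0429), the trended variance (-0.23, 0.0111), array weights (-0.26, 0.0266), the alternative background (-1.37, 0.0182) and without KO 1 (-0.26, 0.0439), in a range of 0.0111 to 0.688. Lists past the threshold numbered 0 with an estimated correlation and with fry. Ehd4 turned to -0.0233 with no background correction, -0.19 with the authors' values, -0.0304 with median centring, -0.0408 with array weights, -0.0802 with the alternative background, -0.0015 without WT 3 and -0.12 without KO 1 (up to 0.0882 without KO 3).

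In Adipose the true analysis gave 36 higher and 29 lower. No background correction gave 150 and 135, the authors' values 78 and 82, no filter 13 and 17, 1 fit over 18 arrays 594 and 704, a trended robust variance 132 and 119, array weights 215 and 195, and the alternative background 112 and 98. Of the 65 calls, 58 were found again with no background correction, 41 with the authors' values and 49 with the alternative background. The section of the slide (positions A to C, D to F) as a block gave 12 and 19, 6 lists, and Cav1 at -4.32 with an adjusted p of 0.0627. No paired analysis was possible because the 2 groups share only 1 replicate number. Leaving out 1 array gave 2 to 58 higher and 6 to 35 lower, 4 to 10 lists, and Cav1 from -4.54 to -4.05. Lists past the threshold numbered 0 with an estimated correlation and 3 with fry. Pacsin3 turned to 0.0462 without WT 1 and 0.0095 without KO 3 (-0.27, the lowest, without KO 5), and Cxcl1 to -0.0112 without KO 3 (0.19, the highest, without WT 4).

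For differences of the knockout effect the alternative background gave 185 (MEF and Liver), 221 (MEF and Adipose) and 284 (Liver and Adipose), and the authors' values 122 for MEF and Adipose and 258 for Liver and Adipose. The section of the adipose slide as a block gave 356 for MEF and Adipose and 546 for Liver and Adipose. The replicate block in MEFs gave 324 for MEF and Liver and 376 for MEF and Adipose. Leaving out 1 array gave 191 to 528, 215 to 845 and 331 to 799. Genes called in both MEF and Liver numbered 19 at unadjusted p under 0.01, 9 with the alternative background, 18 counted in probes and 2 with the replicate block in MEFs. For MEF and Adipose these were 22, 12, 11 and 2, and 8 with the authors' values, and for Liver and Adipose the first 3 were 34, 12 and 18, and 11 with the authors' values.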

Other observations

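The gene families, haemoglobin, sex-linked transcripts and the fit with the section of the adipose slide as a block below were tests chosen only after the result was seen, while the tests that regroup the arrays were fixed before the data were examined.

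In liver, 12 genes of the serpin A family, secreted protease inhibitors and hormone carriers, were measured, of which 2 were called higher (Serpina11, Serpina3m) and 2 lower (Serpina1e, Serpina12). Serpina1e and Serpina3m belong to clusters of closely similar genes, and whether their probes tell these apart was not tested. Among 6 murinoglobulin probes 2 were called lower (Mug2, Mug-ps1) and 4 were positive. In adipose tissue 17 of 19 histocompatibility probes were positive with a median of 0.91, and H2-T10 was the 1 called, beside macrophage markers that were all higher. Transcripts of mitochondrial DNA did not follow the fall of the nuclear oxidative phosphorylation genes in liver, with 12 of 13 positive and a median of 0.29, none called. These family directions were not tested under other scalings.

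Both haemoglobin transcripts were lower in KO liver without passing (Hbb-b1 -1.84 ± 0.49, Hba-a1 -1.77 ± 0.58), so blood content may differ between the liver groups even though the tissues were rinsed, and how far this reaches other genes was not tested. The Y-linked Eif2s3y was detected on every liver and adipose array and both Xist probes on none, so sex does not separate those groups. In MEFs Eif2s3y and 1 of 2 Xist probes were detected on all 6 arrays.

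The arrays of each tissue were regrouped in all 10 ways of splitting 6 arrays into 3 and 3. For probes past the threshold, 1 of 10 splits gave as many calls as the true one in MEFs, in liver and in adipose tissue, that is the true split alone, and the highest other split gave 0, 0 and 1 calls. For gene lists past the threshold, as many were reached by 3 of 10 splits in MEFs (highest other 5, true 4), 1 of 10 in liver (highest other 6, true 7) and 2 of 10 in adipose tissue (highest other 7, true 6). With 10 splits no share under 0.05 can be reached, so regrouping by chance cannot be ruled out by this test alone, and the list counts stand out least. For the difference of the knockout effect, as many probes were reached in 2 of 100 splits for MEF and liver (highest other 385, the true groups with the liver labels mirrored). The share was 1 of 100 for MEF and adipose (highest other 334). For liver and adipose it was 2 of 100 (highest other 832, the true liver groups with adipose WT 2, KO 2 and KO 3 set against the rest). The value 832 lies above the true 511. These shares lay under the 0.05 set beforehand. However, the splits included some that keep the true groups of 1 tissue, whose own effect then fills the difference. The shares therefore cannot tell whether the effect differs between tissues. All splits exchanged arrays without regard to the MEF replicate numbers, in fits without the replicate block.

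The adipose split behind the value 832 sets slide positions D to F (WT 1, WT 4 and KO 5) against A to C, so it follows the section of the slide exactly. The same split gave the 7 lists above the true 6 in adipose tissue, and 0 probe calls there. The value 832 also holds the liver effect, since the true liver groups were kept, and its split was picked as the highest other of 100. Whether the adipose arrays hold a structure other than genotype is therefore left open. With the section of the slide as a block the count was 546 for Liver and Adipose and 356 for MEF and Adipose, against 511 and 375 without it. In Adipose the same block gave 31 calls, 28 of them among the 65, and kept all 6 lists, with glycolysis at -0.54 and oxidative phosphorylation at -0.40. Whether position or something that goes with it is behind these counts was not tested. In MEFs the same sections are the genotype groups, so there the 2 cannot be told apart, and no block can be fitted.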
